A study of Homo sapiens with 6 samples.

How the data were processed

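The series holds 6 poly(A)-selected RNA-seq libraries of SV-HUC-1, an established human urothelial cell line immortalised with SV40. Per the labels, 3 libraries come from cells kept in a blank solution (control) and 3 from cells exposed to 2,6-dichloro-1,4-benzoquinone (DCBQ), for 3 days in both groups. The labels give no concentration of DCBQ. The wider study also measured DNA methylation and hydroxymethylation, and those data were not analysed here.

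The authors deposited 1 table of TPM (expression scaled for gene length and library total) for 60624 Ensembl gene identifiers and 6 columns. Each column name matches 1 library's labels. Every library sums to 1000000, so TPM keeps no record of sequencing depth. The depth is therefore unknown, and no interval or detection floor that needs it is given. Per the submitters' processing notes, the tools included FastQC, Trimmomatic 0.38, HISAT2 2.2.1, StringTie 2.1.7 and DESeq2 1.34.0, with the genome build hg38. The annotation, the use of strand, the handling of multi-mapped reads and the tool that gave the TPM values are not given in the sources used here. Reads from overlapping genes, from near-identical copies and from nuclear copies of mitochondrial genes can therefore be split in ways that the table does not show.

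Gene symbols came from a table of Ensembl identifiers for 42013 identifiers and from GENCODE 29 for another 410, and 18201 identifiers had no symbol. Where several identifiers shared a GENCODE name, the most abundant kept it. Coordinates are those of GENCODE 29 on GRCh38 (hg38), 1-based, in which 58437 identifiers were found.

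Genes with a mean TPM of at least 1 over the 6 libraries were tested on log2(TPM + 1) with limma 3.58.1 (lmFit, then eBayes with a variance trend) in R 4.3.3, with group as the only term. The test was two-sided with Benjamini-Hochberg adjustment over all tested genes, and calls have an adjusted p under 0.05. Fold changes on this scale carry a pseudocount of 1 and understate the change of low genes. Ratios of mean TPM carry no pseudocount. All adjusted p-values of single genes are from this limma fit. Of the 40 gene lists fixed before the data were examined, the 38 with at least 3 tested members were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01. The same test with a correlation estimated per list, and fry, were companions. The share of TPM from the 13 mitochondrially encoded mRNAs was compared by a two-sided exact permutation test over 20 labellings, which cannot give a p below 0.1. No library was identical to another, and no column was left out.

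The rule for named genes was fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among called genes with a symbol and no overlap between the groups. It adds the 4 members with the smallest p of each list and all tested members of the DNA methylation and hydroxymethylation machinery. Y-linked genes and XIST are never named. The rule gives 179 genes, of which the text describes a part. ARRDC4, NQO1, TET1, KIF23, SEC61B, SEC24D, PTPRC, COL1A2, COL3A1, DCN, LUM and PEDS1-UBE2V1 lie outside it and were chosen after other values had been seen.

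The gene and list tests were first checked on simulated data made from the means and spreads of the 16734 tested genes in this comparison, with 200 changed genes. The test recovered 95.5% of the changes of 2 on the log2 scale, 65.2% of the changes of 1 and 26.5% of the changes of 0.5. It made 170 calls, 5 of them on unchanged genes. Both of the 2 lists raised by 0.5 were called, and 0 others. The simulated genes varied independently of each other, so this does not check list calls where members are correlated. The 200 changed genes are also far fewer than the 8857 called in the data.

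The alternatives were pseudocounts of 0.1 and 5, no expression filter, a mean TPM of at least 5, quantile normalization, median-of-ratios scaling, rescaling after leaving out mitochondrially encoded genes, eBayes without the trend, robust eBayes, array weights, the replicate number as a block, and each library left out. Removal of a trend with transcript length and GC content, and a test of protein-coding nuclear genes alone, were added after the data had been seen.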

Results

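The transcriptome of SV-HUC-1 cells, a human urothelial line immortalised with SV40, was measured after 3 days of exposure to DCBQ. DCBQ is a halogenated benzoquinone that forms as a byproduct when drinking water is disinfected. The design has 1 comparison, 3 DCBQ libraries against 3 control libraries, and addresses how the exposure changes gene expression in bladder epithelium. The study placed these data beside maps of DNA methylation and hydroxymethylation, which were not analysed here. Between 26874 and 27350 genes were listed above 0 in each library, and the sequencing depth is unknown because TPM does not keep it. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

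Exposure to DCBQ went with a broad change in expression, led by a loss of amino acid stress genes and a gain of TXNIP. Of 16734 tested genes, 2247 were higher in DCBQ, 6610 were lower and 7877 did not pass the test. A difference of at least 1 on the log2 scale was found for 328 higher and 912 lower genes, 1240 in all. The groups did not overlap for 61.2% of the tested genes, against 10% by chance with 3 against 3. The first principal component held 67.3% of the variance and separated the groups. Pearson correlations of log2 values across genes were 0.984 to 0.986 within groups and 0.952 to 0.955 between them.

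The excess of lower genes depended on scaling. As deposited, 74.6% of the calls were lower, and the median tested gene differed by -0.21. After median-of-ratios scaling 49.1% of the calls were lower (3861 lower and 3995 higher), and after quantile normalization 51.0% (3966 lower and 3814 higher). After leaving out mitochondrially encoded genes it was 61.9% (4929 lower and 3033 higher). Median-of-ratios scaling and quantile normalization centre the libraries on each other by construction. Their near-equal counts were therefore largely set in advance and do not test the excess. Small decreases, near the median of -0.21, cannot be told apart from a shift in scale.

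Among called genes with a symbol and no overlap between the groups, the largest increase on the log2(TPM + 1) scale was in TXNIP (chromosome 1, 145992435 to 145996600, minus strand), which encodes a glucose-responsive inhibitor of thioredoxin. It rose from 6.56 ± 0.37 to 94.5 ± 8.2 TPM (SD, n = 3 per group), a 14.4-fold difference (log2 difference 3.66, SE 0.082, limma adjusted p = 7.3e-08). CA9 (chromosome 9, 35673856 to 35681159), a hypoxia-inducible carbonic anhydrase, rose 15.9-fold from 1.94 ± 0.46 to 30.8 ± 2.5 TPM. IDO1, which degrades tryptophan, rose 12.6-fold to 22.9 ± 1.6 TPM, and RGS16, a regulator of G protein signalling, rose 9.97-fold to 40.6 ± 2.1 TPM. FOS rose from 29.3 to 205 ± 19 TPM and ID3, an inhibitor of helix-loop-helix factors, 5.79-fold to 277 ± 12 TPM. The adhesion receptor gene ADGRF1 rose 8.96-fold, TNFSF10, which encodes the death ligand TRAIL, 8.70-fold, and the interferon-inducible RTP4 6.28-fold. CD99 rose 10.5-fold with a wide spread among the DCBQ libraries (65.0 ± 41.0 TPM against 6.21 ± 0.44). It lies in the pseudoautosomal region, where reads can align to more than 1 copy.

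Among the same kind of genes, the largest decrease on the log2(TPM + 1) scale was in ASNS (chromosome 7, 97852118 to 97872542, minus strand), which encodes asparagine synthetase. It fell 26.1-fold, from 324 ± 11 to 12.4 ± 1.3 TPM (log2 difference -4.60, SE 0.074, limma adjusted p = 2.7e-08). CHAC1 (chromosome 15, 40952962 to 40956519), which degrades glutathione, fell 33.2-fold from 69.8 ± 4.8 to 2.11 ± 0.48 TPM. The pseudokinase gene TRIB3 fell 14.9-fold from 463 ± 12 to 31.2 ± 2.9 TPM, and PSAT1, an enzyme of serine synthesis, 11.4-fold from 648 ± 6.2 to 56.8 ± 2.0 TPM. SLC7A11, the cystine transporter, fell 15.5-fold from 39.9 ± 1.9 to 2.57 ± 0.20 TPM. The hormone gene ADM2 fell 33.4-fold, the inducible chaperone gene HSPA6 19.4-fold, the actin-binding TAGLN 14.8-fold, the YAP target ANKRD1 14.5-fold and the kinesin gene KIF1A 26.1-fold. Reads of HSPA6 can be shared with its close paralogs.

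Of the 38 gene lists tested, 14 were called by camera with the preset correlation, 11 higher and 3 lower. No list was called with an estimated correlation, where the smallest adjusted p was 0.146. That version takes its degrees of freedom from the 6 libraries and not from the genes, so small p-values are hard to reach. The hypoxia list had an estimated correlation of -0.0039, below the preset 0.01, yet its camera adjusted p went from 9.8e-07 to 0.146. The loss of calls therefore does not show that correlated members account for them. Regrouping the same 6 libraries in the 9 other ways, each of which sets 2 libraries of one group and 1 of the other against the rest, gave 7 to 13 called lists. The counts adjusted over the list alone were the same as those over all tested genes in 28 lists, and the other 10 are given where they occur. The list test compares a list with the other genes, and 14 of the 24 uncalled lists had a median below 0 with a test direction of higher. The called lists had a test, median and mean of the same sign. Median and mean differed in sign for the histone, AHR and NF-kB lists. The majority of called members turned from lower to higher, or the reverse, under median-of-ratios scaling in 12 lists and under quantile normalization in 9, none of them a called list.

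**Figure D1:**
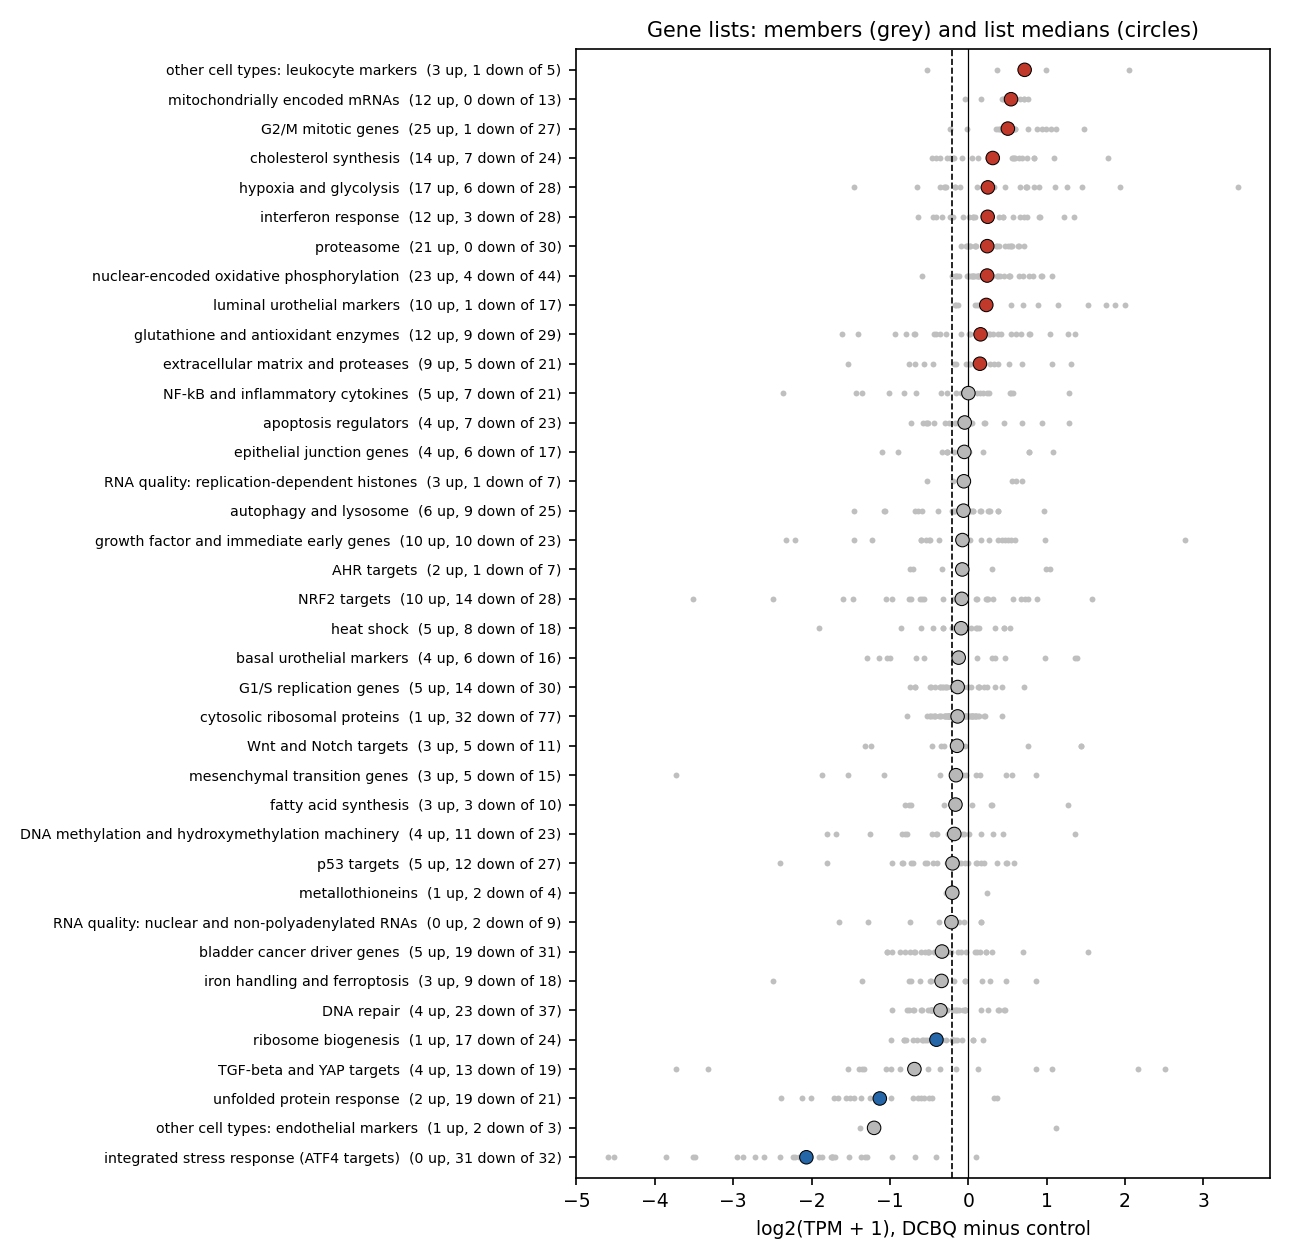
Each row is 1 of the 38 tested gene lists, with the difference in log2(TPM + 1), DCBQ minus control, of each tested member as a grey dot and the list median as a circle, red for a list called higher by camera with the preset correlation, blue for lower and grey for not called. The solid line marks 0 and the dashed line the median of all tested genes (-0.21), and the row labels give the members that were higher and lower. The integrated stress response list lies farthest to the left, with a median of -2.07.

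The integrated stress response, through which cells slow translation and induce ATF4 targets when amino acids run short, was lower in DCBQ almost throughout. Of 32 tested ATF4 targets 31 fell and 0 rose, with a median of -2.07 (camera adjusted p = 5.2e-15, and adjusted p = 0.146 with an estimated correlation). Beside ASNS, TRIB3 and PSAT1, the secreted glycoprotein gene STC2 fell 7.82-fold from 610 ± 20 to 77.9 ± 3.7 TPM. The unfolded protein response, which raises chaperones of the endoplasmic reticulum, was lower too, with 19 of 21 members falling and 2 rising (SEC61B and SEC24D, which act in transport into and out of the endoplasmic reticulum). Its median was -1.13 (camera adjusted p = 3.7e-06, and adjusted p = 0.148 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell 4.37-fold from 1378 ± 17 to 315 ± 11 TPM, and XBP1 fell 5.31-fold, HSP90B1 2.84-fold and PDIA4 2.76-fold. Cytosolic heat shock genes were mixed, with 5 higher and 8 lower of 18 (camera adjusted p = 0.708), and 7 higher and 3 lower under median-of-ratios scaling. DNAJB1 fell 3.77-fold from 999 ± 21 to 265 ± 0.69 TPM and HSPH1 fell 1.82-fold, while HSPA8 rose 1.38-fold.

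Genes of the oxidative and electrophile response went both ways. Of 28 NRF2 targets 10 were higher and 14 lower (camera adjusted p = 0.608), and the majority turned to 13 higher and 11 lower under median-of-ratios scaling and under quantile normalization. HMOX1, the inducible haem oxygenase, fell 5.70-fold from 333 ± 14 to 58.4 ± 2.9 TPM, and TXNRD1, which reduces thioredoxin, 2.79-fold. PRDX1, a peroxidase, rose 2.99-fold from 174 ± 8.8 to 520 ± 26 TPM. NQO1, a quinone reductase, had a log2 difference of 0.23 (adjusted p = 0.0027). Glutathione and antioxidant enzymes had 12 higher and 9 lower of 29, with a median of 0.16 (camera adjusted p = 0.011, and adjusted p = 0.332 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.096) and median-of-ratios scaling (adjusted p = 0.058). GSTP1 rose 1.72-fold and catalase (CAT) 2.11-fold, while GPX1 fell 1.74-fold and GSTM4, one of a family of close paralogs, 2.85-fold. Of 7 AHR targets 2 were higher and 1 lower (camera adjusted p = 0.406). CYP1A1 rose 2.34-fold to 9.03 ± 0.75 TPM and UGT1A6, which shares exons with its gene cluster, 2.01-fold, while NFE2L2, which encodes NRF2, fell 1.67-fold. AHRR had 1.72 ± 0.75 TPM in control and 0.65 ± 0.35 in DCBQ (adjusted p = 0.064). Iron handling and ferroptosis genes had 3 higher and 9 lower of 18, 3 and 10 adjusted over the list alone (camera adjusted p = 0.514). The transporter gene SLC39A14 fell 2.60-fold and ferritin light chain FTL 1.66-fold, while the transferrin receptor TFRC rose 1.83-fold. Of 4 metallothionein list genes 1 was higher and 2 lower, 1 and 3 adjusted over the list alone (camera adjusted p = 0.989), and 1 higher and 0 lower under median-of-ratios scaling. MT2A (0.23 on the log2 scale) was called as deposited and lost its call in 3 of 18 alternatives. The call of MT1F (-0.29) was lost in 11 of 18, and neither it nor that of the zinc exporter SLC30A1 (-0.24) held under median-of-ratios scaling or quantile normalization.

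**Figure D2:**
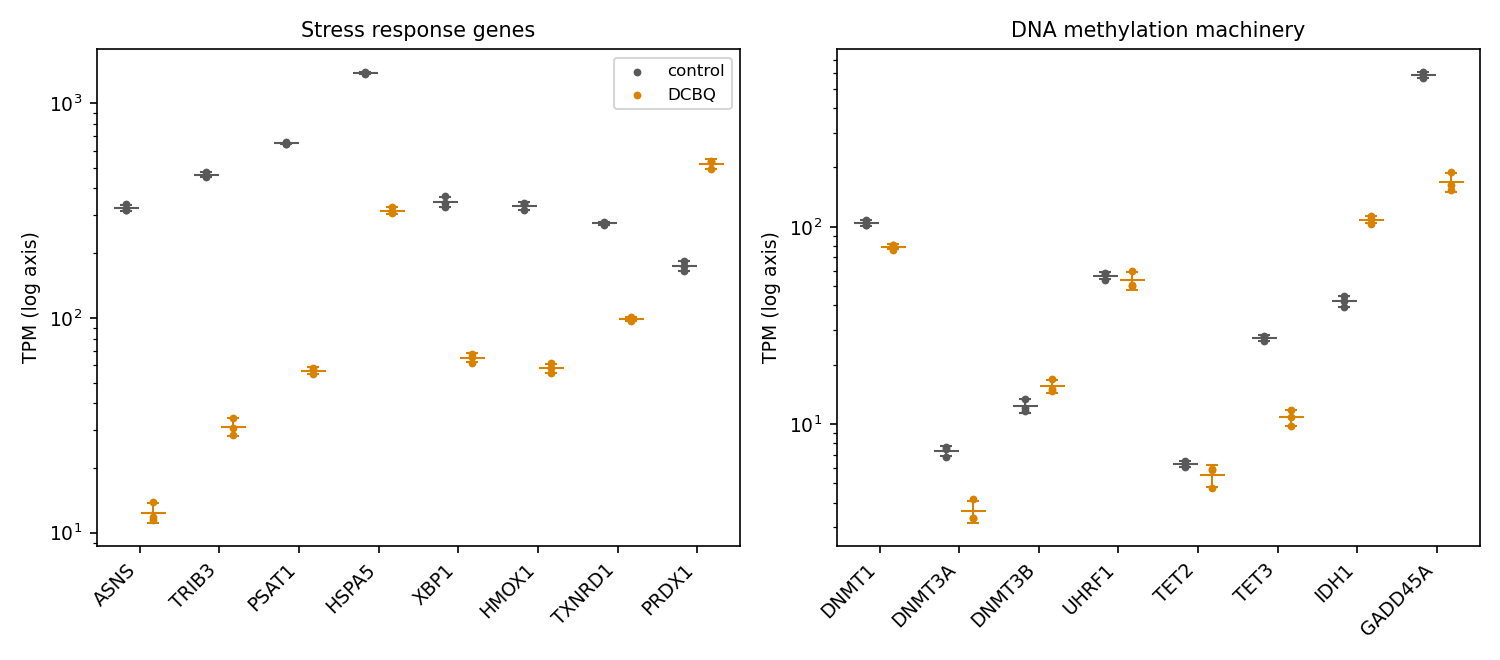
TPM on a log axis in each library, control in grey and DCBQ in orange, for 8 stress response genes (left) and 8 genes of the DNA methylation machinery (right). Points are libraries, and bars give the mean and SD of the 3 libraries of a group. TET3 and DNMT3A lie lower and IDH1 higher in all 3 DCBQ libraries than in any control library.

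Among the genes that write, read and remove DNA methylation, the demethylating oxidase gene TET3 and the de novo methyltransferase gene DNMT3A fell and IDH1 rose. Of 23 tested members of this list 4 were higher, 11 lower and 8 did not pass (median -0.18, camera adjusted p = 0.514), and under median-of-ratios scaling 5 were higher and 7 lower. TET3 fell 2.52-fold, from 27.3 ± 0.90 to 10.8 ± 1.0 TPM (log2 difference -1.26, SE 0.086, limma adjusted p = 1.3e-05). DNMT3A fell 2.02-fold from 7.30 ± 0.46 to 3.62 ± 0.47 TPM (adjusted p = 0.00072). The maintenance methyltransferase DNMT1 fell 1.32-fold from 104 ± 3.7 to 79.2 ± 2.4 TPM, and its difference was -0.40 as deposited and -0.15 after median-of-ratios scaling (adjusted p = 0.019). DNMT3B rose 1.26-fold from 12.4 ± 0.96 to 15.6 ± 1.2 TPM (adjusted p = 0.022), a call lost in 3 of 18 alternatives, each with 1 library left out. IDH1, which makes the cofactor 2-oxoglutarate that TET enzymes use, rose 2.60-fold from 41.9 ± 2.6 to 109 ± 4.9 TPM, and the mitochondrial IDH2 rose 1.37-fold. GADD45A and GADD45B, stress genes linked to active demethylation, fell 3.48-fold and 3.29-fold. UHRF2, a reader of hydroxymethylcytosine, fell 1.73-fold. The calls of D2HGDH (-0.46), MAT2A (-0.26), MBD1 (-0.41) and MBD4 (-0.24) were lost under median-of-ratios scaling, and that of AHCY (0.16) was lost in 5 of 18 alternatives. TET2 had a difference of -0.17 (adjusted p = 0.28) and UHRF1 of -0.08 (adjusted p = 0.41). TDG, ZBTB33, SMUG1 and MBD3 lay between -0.18 and -0.06, and MBD2 at 0.01, none of them passing. The differences of TET2, UHRF1, TDG, ZBTB33, SMUG1 and MBD3 turned positive under median-of-ratios scaling. TET1 was below the expression filter at 0.93 TPM in control and 0.73 in DCBQ. Of the 32 germline and cancer-testis genes that methylation commonly silences, 2 passed the filter, too few for a list test. SSX1 rose from 0.26 ± 0.026 to 2.01 ± 0.92 TPM (log2 difference 1.22, adjusted p = 0.0039), and TDRD1 had 9.43 ± 1.4 TPM in control and 9.75 ± 0.59 in DCBQ.

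Mitotic genes rose together. Of 27 G2/M genes 25 rose and 1 fell (KIF23), with a median of 0.50 (camera adjusted p = 1.4e-15, and adjusted p = 0.148 with an estimated correlation). The mitotic kinesin gene KIF20A rose 2.84-fold from 33.4 ± 2.5 to 94.6 ± 6.3 TPM, CDC20 rose 2.08-fold, AURKA 1.92-fold and CCNB1 1.85-fold. Replication genes of the G1/S transition had 5 higher and 14 lower of 30, 6 and 14 adjusted over the list alone (camera adjusted p = 0.974), and 12 higher and 6 lower under median-of-ratios scaling. The licensing factor CDT1 fell 1.61-fold, E2F1 1.60-fold and DTL 1.70-fold, while PCNA rose 1.27-fold. DNA repair genes had 4 higher and 23 lower of 37, 4 and 24 adjusted over the list alone (camera adjusted p = 0.305), and 8 higher and 11 lower under median-of-ratios scaling. ERCC2, a helicase of nucleotide excision repair, fell 1.98-fold, XPA 1.66-fold and XRCC1 1.41-fold, while XRCC5 rose 1.31-fold. Among 27 p53 targets 5 were higher and 12 lower (camera adjusted p = 0.708), and 8 higher and 9 lower under median-of-ratios scaling. The largest decreases, in SESN2 (5.59-fold) and GADD45A, are in genes also induced by ATF4. PLK2 fell 1.78-fold and GDF15, which is also on the list of ATF4 targets, 2.00-fold. Apoptosis regulators had 4 higher and 7 lower of 23 (camera adjusted p = 0.514), and 10 higher and 6 lower under median-of-ratios scaling. The survival gene BCL2L1 fell 1.43-fold and the death effector BBC3 1.71-fold. Of 31 bladder cancer driver genes 5 were higher and 19 lower (camera adjusted p = 0.514), and 9 higher and 12 lower under median-of-ratios scaling. The acetyltransferase gene CREBBP fell 2.07-fold and CCND1 1.60-fold.

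Luminal urothelial markers were higher, with 10 rising and 1 falling of 17 and a median of 0.23 (camera adjusted p = 3.7e-07, and adjusted p = 0.183 with an estimated correlation). UPK1B, which encodes a uroplakin of the umbrella cell membrane, rose 4.15-fold from 19.8 ± 1.9 to 81.9 ± 5.5 TPM. The transcription factor genes GRHL3 and ELF3 rose 3.82-fold and 2.90-fold and KRT19 2.21-fold. Basal markers were mixed, with 4 higher and 6 lower of 16, 5 and 6 adjusted over the list alone (camera adjusted p = 0.514), and 7 higher and 6 lower under median-of-ratios scaling. KRT5 rose 2.59-fold from 117 ± 2.1 to 303 ± 9.6 TPM and S100A2 2.65-fold, while KRT17 fell 2.01-fold and the laminin gene LAMB3 2.46-fold. Junction genes had 4 higher and 6 lower of 17 (camera adjusted p = 0.618), and 6 higher and 2 lower under median-of-ratios scaling. CLDN1 fell 2.16-fold and the protease gene PRSS8 1.88-fold, while ST14 rose 1.71-fold and OVOL1 1.75-fold. Mesenchymal transition genes had 3 higher and 5 lower of 15 (camera adjusted p = 0.869), and 6 higher and 4 lower under median-of-ratios scaling. The receptor kinase gene AXL fell 2.90-fold and SNAI2 3.83-fold, while TGFBI rose 1.82-fold. TGF-beta and YAP targets had 4 higher and 13 lower of 19, 4 and 14 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 0.206). This list was called lower under median-of-ratios scaling (adjusted p = 0.042) and quantile normalization (adjusted p = 0.022). The matricellular gene CCN1 fell 2.53-fold. Matrix and protease genes had 9 higher and 5 lower of 21, 10 and 6 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.026, and adjusted p = 0.520 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.092). PLAT rose 2.49-fold and TIMP1 1.62-fold, while LAMA3 fell 2.91-fold and MMP14 1.48-fold. Wnt and Notch targets had 3 higher and 5 lower of 11 (camera adjusted p = 0.708), and 4 higher and 2 lower under median-of-ratios scaling. NOTCH3 rose 2.93-fold and HES1, a Notch target, 2.71-fold, TCF7 rose 1.84-fold and the Wnt inhibitor DKK1 fell 2.54-fold.

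Interferon-stimulated genes were higher, with 12 rising and 3 falling of 28, 12 and 5 adjusted over the list alone, and a median of 0.25 (camera adjusted p = 1.5e-05, and adjusted p = 0.349 with an estimated correlation), and 18 higher and 0 lower under median-of-ratios scaling. SAMD9 rose 2.64-fold, IFIT3 1.91-fold, OAS1 1.90-fold and BST2 1.49-fold. Inflammatory genes under NF-kB control had 5 higher and 7 lower of 21 (camera adjusted p = 0.514), and 8 higher and 6 lower under median-of-ratios scaling. The cytokine gene IL1A fell 6.20-fold from 24.2 ± 0.29 to 3.90 ± 0.42 TPM, RELB fell 2.65-fold and NFKB2 1.60-fold, while the neutrophil chemokine CXCL8 rose 2.46-fold from 69.5 ± 7.4 to 171 ± 17 TPM. Growth factor and immediate early genes had 10 higher and 10 lower of 23 (camera adjusted p = 0.406). While FOS rose, HBEGF fell 5.31-fold. SPRY4, a feedback gene of ERK signalling, fell 5.76-fold and the transcription factor gene ETV5 2.91-fold.

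Genes of glycolysis and the hypoxia response were higher, with 17 rising and 6 falling of 28 and a median of 0.25 (camera adjusted p = 9.8e-07, and adjusted p = 0.146 with an estimated correlation). Beside CA9, LDHA rose 3.82-fold from 647 ± 8.3 to 2471 ± 43 TPM, PGK1 2.76-fold and PKM 2.39-fold. Nuclear-encoded subunits of the respiratory chain had 23 higher and 4 lower of 44, with a median of 0.24 (camera adjusted p = 2.5e-09, and adjusted p = 0.183 with an estimated correlation), and 35 higher and 0 lower under median-of-ratios scaling. NDUFA1 rose 1.94-fold, NDUFB3 1.78-fold and NDUFA2 1.58-fold, and ATP5MC1 rose too. Of the 13 mitochondrially encoded mRNAs 12 rose and 0 fell, with a median of 0.55 (camera adjusted p = 2.7e-09, and adjusted p = 0.201 with an estimated correlation), while under quantile normalization 6 were higher and 1 lower and the list was not called (adjusted p = 0.096). MT-CYB rose 1.70-fold, MT-ATP6 1.64-fold, and MT-CO2 1.63-fold, and MT-CO3 rose too. Together these mRNAs made up 17.0% ± 0.45 of all TPM in control and 24.1% ± 0.33 in DCBQ, a difference of 7.07 points with no overlap between the groups (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). Cholesterol synthesis genes had 14 higher and 7 lower of 24 and a median of 0.31 (camera adjusted p = 1.5e-05, and adjusted p = 0.304 with an estimated correlation), and 16 higher and 1 lower under median-of-ratios scaling. HMGCS1 rose 3.49-fold from 41.9 ± 3.7 to 147 ± 7.9 TPM, INSIG1 2.16-fold and MSMO1 1.80-fold. Fatty acid synthesis genes had 3 higher and 3 lower of 10 (camera adjusted p = 0.689). The desaturase genes SCD and FADS1 fell 1.76-fold and 1.69-fold and the regulator SREBF1 1.67-fold, while ELOVL6 rose 2.78-fold.

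Proteasome subunits were higher, with 21 rising and 0 falling of 30 and a median of 0.24 (camera adjusted p = 1.3e-09, and adjusted p = 0.183 with an estimated correlation). PSMA2 and PSMA5 rose 1.57-fold, PSMA3 1.48-fold and PSMB1 1.47-fold. Ribosome biogenesis genes were lower, with 1 rising and 17 falling of 24, 1 and 18 adjusted over the list alone, and a median of -0.41 (camera adjusted p = 0.014, and adjusted p = 0.253 with an estimated correlation). That call ended under median-of-ratios scaling (adjusted p = 0.10). The helicase gene DDX21 fell 1.99-fold, DKC1 1.52-fold and NOP58 1.44-fold, and MYBBP1A fell too. Cytosolic ribosomal proteins, which have many near-identical pseudogenes, had 1 higher and 32 lower of 77, 1 and 29 adjusted over the list alone (camera adjusted p = 0.663). Under median-of-ratios scaling they turned to 18 higher and 4 lower. Under quantile normalization they were 3 higher and 34 lower, and the list was called lower (camera adjusted p = 0.011). RPL12 fell 1.72-fold and RPL3 1.44-fold. Autophagy and lysosome genes had 6 higher and 9 lower of 25 (camera adjusted p = 0.608), and 12 higher and 6 lower under median-of-ratios scaling. The autophagy genes ULK1, SQSTM1 and MAP1LC3B fell 2.79-fold, 2.12-fold and 2.11-fold, while the lysosomal enzyme gene GLA rose 1.99-fold.

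Markers of cell types that a pure urothelial culture should lack mostly stayed low. Of 15 leukocyte markers 5 were tested, 3 higher and 1 lower, with a median of 0.72 (camera adjusted p = 0.016, and adjusted p = 0.332 with an estimated correlation), a call lost under both scalings, without mitochondrially encoded genes and at a mean TPM of at least 5. The members that rose were CORO1A (3.00 ± 0.37 to 15.6 ± 2.8 TPM), CD68 (3.85 ± 0.81 to 8.56 ± 0.37) and CD14 (0.94 ± 0.29 to 2.18 ± 0.27), which act in the actin cortex, in lysosomes and in lipopolysaccharide binding. LAPTM5 fell from 6.36 ± 1.6 to 4.02 ± 0.37 TPM, a call lost in 9 of 18 alternatives, and the pan-leukocyte gene PTPRC was at most 0.068 TPM in any library. Of 10 endothelial markers 3 were tested, 1 higher (CDH5, 2.49-fold) and 2 lower (ROBO4, 2.70-fold, and KDR, 6.74-fold), with a camera adjusted p of 0.608. Of 10 fibroblast markers only COL1A1 passed the filter and rose 2.25-fold to 15.1 ± 1.1 TPM, while COL1A2, COL3A1, DCN and LUM were listed at 0 in all 6 libraries. Replication-dependent histones, which typically lack a poly(A) tail in intact RNA, had 3 higher and 1 lower of 7 (camera adjusted p = 0.128), with H2BC12 1.49-fold and H1-2 1.67-fold higher. A list of nuclear RNAs, non-polyadenylated RNAs and small nucleolar RNA host genes had 0 higher and 2 lower of 9 (camera adjusted p = 0.710). The 2 were the host genes SNHG1 and GAS5, which fell 3.17-fold and 2.42-fold. MALAT1 (161 ± 14 TPM in control, 139 ± 18 in DCBQ) and NEAT1 (447 ± 187 in control, 248 ± 9.3 in DCBQ) did not pass. They were called lower in 3 and 4 of 18 alternatives.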

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

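Calls depended on scaling. The counts of higher and lower genes stayed within 1.5 times the reported 2247 and 6610 except under quantile normalization (3814 higher, 3966 lower) and median-of-ratios scaling (3995 higher, 3861 lower). These centre the libraries by construction, and moved the median gene from -0.21 to -0.01 and -0.004. Under median-of-ratios scaling 6108 of the 8857 calls kept their direction, 2740 were lost and 9 were called the other way, with a change of sign in 380. Under quantile normalization 6198 kept it, 2659 were lost and 0 were called the other way, with a change of sign in 228. Leaving out each library in turn gave 1883 to 2123 higher and 5675 to 6443 lower genes. The 1240 genes past a difference of 1 became 1871 with a pseudocount of 0.1 and 479 with one of 5, since the pseudocount sets how far low genes can move. The 14 called lists became 0 with an estimated inter-gene correlation, a version that also has fewer degrees of freedom. They became 31 with fry, which asks whether a list moves at all. The other alternatives gave 12 to 20 lists, most without an expression filter. Neither eBayes option enters camera, and the protein-coding subset, added after the data had been seen, was run for genes only, so these give no list value. The G2/M, ATF4 target, unfolded protein, proteasome, respiratory chain, luminal, hypoxia, interferon and cholesterol lists were called in all 16 alternatives that used camera with the preset correlation. Without an expression filter the DNA repair, DNA methylation, bladder driver, TGF-beta and YAP, ribosomal protein and fibroblast lists were called as well.

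Of 166 called genes among the 179 named, 153 kept call and direction in each setting. Among the others, differences turned positive under quantile normalization for SLC30A1 (0.034), TDG (0.10), ZBTB33 (0.13), TET2 (0.055), SMUG1 (0.14), UHRF1 (0.13) and MBD3 (0.15). Under median-of-ratios scaling they did so for MT1X (0.071), MBD4 (2.5e-04), TDG (0.057), ZBTB33 (0.086), TET2 (0.042), SMUG1 (0.093), UHRF1 (0.16), MBD3 (0.18) and MALAT1 (0.028). Without mitochondrially encoded genes UHRF1 (0.049) and MBD3 (0.071) turned, and MBD3 also with the length and GC trend removed (0.11), an alternative chosen after seeing the data. Leaving out 1 library moved MBD3 between -0.12 and 0.019, MBD2 between -0.016 and 0.027 and TDRD1 between -0.0090 and 0.16. Of these, only SLC30A1 and MBD4 were called as deposited, and the cause was not tested beyond the shift of the median gene. MT-CO2, the most abundant, was 0 by construction under quantile normalization.

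Whether replicate numbers pair the libraries could not be decided from so few libraries, and no test was run. Deviations of same-numbered libraries correlated at -0.037, 0.045 and 0.046, while 4 of 6 libraries correlated best with their own number. With the replicate block 2156 genes were higher, 6344 lower and 14 lists called. The difference in mitochondrial mRNA share was 7.07 points with the block, 5.49 without the most abundant mRNA and 6.87 to 7.31 with a library left out, in designs too small for a p under 0.05. Depth is unknown, so no limit from counting error can be given.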

Other observations

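The tests of gene length and of exchanged labels were chosen only after the result they bear on had been seen. The other tests were written down before. The rule that a bound must be passed by more than 2 SE was added after the values had been seen, and it changed only the length verdict, from not accounting for the excess to undecided. The ARRDC4 test, and the test of the excess of lower genes without mitochondrially encoded genes, were read as undecided after their values had been seen. The TPM limits of the third pattern were set when its test was run.

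With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes higher and genes lower in DCBQ the real split gave 2247 and 6610, and the highest other split gave 1, counting the larger direction of each. For genes changed by at least 1 the real split gave 1240 and the highest other 1. For gene lists the real split called 14 and the highest other 13. Each other split sets 2 libraries of one group and 1 of the other against the rest, so part of the difference between the groups stays in it. In each of these 4 cases 1 of the 10 splits, the real one, gave as many.

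The first pattern is the excess of lower genes, 74.6% of the calls. Mitochondrially encoded genes took a larger share of TPM. Leaving them out brought the share of lower genes to 61.9% (binomial SE 0.54), above the bound of 60 set beforehand. That SE treats genes as independent, though the scaling of 1 library moves them together. Leaving out single libraries moved the share as deposited between 73.6% and 76.3%, and the rescaled share was not recomputed in this way. The bound of 60 was passed by more than 2 SE. After the values had been seen, whether 61.9% clears it was read as undecided, because the spread between libraries is not in that SE. The larger mitochondrial share accounts for part of the excess at most. Gene length bias remains open: the share of lower genes was 60.4% (SE 1.5) in the fifth of genes with the shortest longest transcript and 85.1% in the fifth with the longest, and the first value lies too near its bound of 60 to decide. Removing the length and GC trend left 74.1% lower, but that correction keeps the mean of each library, so it cannot decide either. Because TPM is relative, an actual fall in the RNA of most genes cannot be separated from scaling.

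The second pattern is the fall of ATF4 and unfolded protein response genes, with a median of -1.71 over 53 tested members. Without mitochondrially encoded genes the median was -1.61 (bootstrap SE 0.16). All such genes held 21.5% of TPM in control and 28.4% in DCBQ, and rescaling moves every other gene of a library alike. The outcome was thus set by these shares, which are too close to each other to account for the fall. An exchange of the control and DCBQ labels for all 6 libraries cannot be told apart from a true fall by the test used: the 27 NRF2 targets that are not ATF4 targets lay 0.17 (bootstrap SE 0.21) above the median gene, with 16 above and 11 below. Nutrients running down in the control cultures would raise ARRDC4, which shares the glucose sensor of TXNIP, in DCBQ, and it rose from 6.34 ± 0.68 to 20.7 ± 0.61 TPM (log2 difference 1.57, SE 0.096, limma adjusted p = 7.4e-06), but a rise of ARRDC4 goes with that of TXNIP and says nothing of the ATF4 targets, so the test does not decide. A direct action of DCBQ, untested here, stays open as well.

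The third pattern is 39 tested genes that are below 0.1 TPM in 1 library and at least 5 TPM in another of the same group. PEDS1-UBE2V1, a readthrough gene chosen after its values were seen, is one: it was listed at 122, 0 and 23.7 TPM in the DCBQ libraries and at 0 in the controls. Reads shared between overlapping annotated genes would make such genes overlap others on the same strand more often. Of the 37 with an annotation 91.9% did, against 31.1% of other tested genes, a ratio of 2.96 (two-sided Fisher's exact p = 1.5e-14). Their values may therefore reflect how reads were assigned between overlapping genes, and 2 of the 39 are among the called genes. No biological explanation was tested for this pattern.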
